A study of Mus musculus with 8 samples.

How the data were processed

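ATAC-seq, in which the Tn5 transposase cuts and tags DNA that is not covered by nucleosomes or other proteins, was run on Hepa-1c1c7 cells, an established mouse hepatoma line. Per the labels, the cells received potassium chromate, a source of hexavalent chromium, for 72 h at 0, 0.1, 0.5 or 1 µM, with 2 libraries per dose and 8 libraries in all. Nuclei were transposed for 30 minutes, the libraries were amplified with 9 PCR cycles, and sequencing to about 75 M read pairs of 100 bp was named. The actual depth of each library is unknown here, since the files hold regions and no read counts. Nothing in the labels says whether the 2 libraries of a dose came from separate cultures.

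The files analysed are 3 lists of genomic regions, 1 for each treated dose. Each list is attached to both libraries of its dose, and its name pairs that dose with the untreated cells, so the control is named in every list. Whether the libraries of a dose were pooled or combined in another way is not given in the sources used here. No list of the untreated cells was used here. A list therefore has no replicate error, no library could be left out in turn, and no difference between doses could be set against the spread between replicates. Bowtie2, Picard, MACS2 and the build mm10 are named in the submitters' processing notes, without a version or a role for each. How the control was used, which threshold was set and whether a listed region must be more open in treated than in control cells are not given in the sources used here. The list names carry a tag that begins with q and words for filtering and uniqueness, whose meaning is not given in the sources used here. A region missing from a list is thus not shown to be closed. The read shift for Tn5 and the removal of duplicates are likewise not given in the sources used here. The region names number each list in order with gaps, of 328 names at 0.1 µM, 342 at 0.5 µM and 369 at 1 µM, so some regions had been taken out before deposit.

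Each region carries a deposited score, a whole number of at least 4 whose scale the authors do not state. Apart from the check that follows, tests used it only to rank regions within a list. Medians and scores of single regions are also given, as deposited. The score was checked on regions that overlapped exactly 1 region of another list. Among such pairs with a mean width of 1000 bp or more, 19.9% (0.1 against 0.5 µM), 15.8% (0.1 against 1 µM) and 20.7% (0.5 against 1 µM) differed in score by more than 4 times after the median difference was removed. From 500 to 1000 bp these shares were 4.71%, 4.95% and 5.41%, and under 500 bp 1.99%, 1.76% and 2.23%. In the pairs of 1000 bp or more that differed so much, the region with the lower score was the narrower one in 33.3%, 21.7% and 23.2% of cases. From 500 to 1000 bp it was the narrower one in 28.9%, 22.3% and 25.8%. The score is therefore not a dependable measure of strength in wide regions, and a smaller part of those of 500 to 1000 bp shares the fault. Scores of single genes are thus not read as differences between doses. For the same reason the comparison of shared and list-specific regions, the strongest part of the lists, and in the closing section the tests on ranks and on the shorter 0.5 µM list, were repeated with the region's width. The named regions and genes and the 100 regions with the highest score were chosen by score alone, although many of them are wide.

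The 1 µM libraries carry another prefix in their labels (N503) than all other libraries (N502). The labels do not explain the prefix, and it cannot be told apart from the dose of 1 µM. Since all lists share the control libraries, part of any overlap between lists may come from them. Region lists allow neither a split of the controls nor a simulation of unchanged groups.

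Positions were compared with a RefSeq gene table of GRCm38.p6, the assembly to which mm10 corresponds, and are given as 1-based mm10 coordinates. The table gives each gene's start and end but no strand, exon or sequence. A promoter could therefore not be told from the other end of a gene. In place of promoter, exon, intron and intergenic classes, each region midpoint was put at a gene end (within 1 kb of either end of a protein-coding gene), inside a gene, or between genes. A search for 17 sequence motifs, CTCF among them, was planned and not run, because no genome sequence was used here. The background for genes was 21631 protein-coding genes of chromosomes 1 to 19 and X, which includes genes silent in this line. No list holds a region on chromosome Y.

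Overlap was the share of the shorter list's regions touched by at least 1 bp of the longer list, compared with 1000 random placements of the shorter list's regions on their own chromosomes (one-sided, smallest possible p 0.001). Location shares were compared with 1000 placements in the same way (two-sided, smallest possible p 0.002), without avoiding assembly gaps. Between doses, location shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 3 locations and 3 pairs. The rank of shared and list-specific regions was compared by a permutation test with 100000 resamples (smallest possible p 1e-05). For 16 gene lists, the share of genes with a region within 1 kb of either end was compared with all other genes by Fisher's exact test, two-sided, adjusted over lists and doses. Regions are not replicates, so these tests compare lists. Windows of 1 Mb with at least 10 regions were compared between each list and the other 2 in the same manner, over 1307 windows. The 95% intervals of shares are Wilson intervals, those of differences use the normal approximation, and all cover counting error only. For locations and windows, the tests and intervals between doses treat the lists as independent, although many regions are listed at several doses. Their p-values and widths are therefore not exact.

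The named regions are the 10 with the highest score in each list and the 10 listed at every dose with the best mean rank. The named genes are up to 4 members of each gene list, ordered by the number of doses with a region and then by rank, together with Cyp1a1, Hmox1, Nqo1, Mt1, Mt2, Cdkn1a, Ctcf and Alb. Of the genes selected by this rule, 1 is not reported here. A gene's score is that of its best-ranked region at either end, which need not be the same region at each dose. These rules, the gene lists and a first set of alternative settings were fixed before the data were examined. That first set held another overlap rule, a window of 2.5 kb, all annotated genes, the gene body with 10 kb either side (in place of 10 kb upstream), the stronger 50% of each list by score, equal numbers of strongest regions, and width in place of score. After seeing the data, rankings by width for the overlap of the strongest regions, the locations, the gene lists and the closing section's tests on ranks and on the shorter 0.5 µM list, random shifts of up to 500 kb, gene draws from the same chromosomes, and runs without chromosome 15 or without olfactory and vomeronasal receptor genes were added.

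Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The tests were tried on simulated data. For the gene lists, the regions' genes were shuffled over the 21631 genes in 100 draws and the list of 30 cell cycle genes was given a set share: with 50% of its genes holding a region, 71.7% of the tests called it, with 40% only 23.3% did, and 0.111% and 0.133% of the tests of other lists were called. A list near 40% can thus be missed. Independent random lists passed the overlap test in 8 of 100 draws, and copying 1% of the 11130 regions was found in 100 of 100. A window with 3 times as many regions of 1 list was found in 60% of 20 draws over 1307 windows. The excess was planted only in the 136 windows with 50 to 100 regions over all lists. How often it would be found in windows with fewer or more regions was not tried.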

Results

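Hepa-1c1c7 mouse hepatoma cells were treated for 72 h with potassium chromate at 0.1, 0.5 or 1 µM, and their accessible chromatin was mapped by ATAC-seq. Each dose had 2 libraries, as did the untreated cells. The title of the series points to chromatin accessibility and CTCF sites in promoters after hexavalent chromium. The deposited regions come as 1 list per treated dose, attached to both of its libraries and paired by name with the untreated cells, so no value below has a replicate error. Whether a listed region gained accessibility over the control is not given in the sources used here.

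Regions were listed on chromosomes 1 to 19 and X at every dose. The 0.1 µM list held 14401 regions, the 0.5 µM list 11130 and the 1 µM list 15894, which covered 6.04, 4.34 and 6.91 Mb. The number did not rise step by step with dose: 1 µM gave 1.43 times and 0.1 µM 1.29 times as many regions as 0.5 µM. The median width was 339, 324 and 353 bp in order of dose. The median score, the authors' own number per region, was 11, 10 and 13. With 1 list per dose there is no spread between replicates against which to set these numbers, and the prefix of the 1 µM libraries differs from that of all others.

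Chromosome 15 had the highest density of listed regions at each dose. It held 18.1, 16.3 and 20.4 regions per Mb at 0.1, 0.5 and 1 µM, against 4.99, 3.76 and 5.49 per Mb over all other chromosomes, a ratio of 3.63, 4.33 and 3.71. Among the 100 regions with the highest score, 26, 28 and 30 lay on chromosome 15, while its median region ranked below that of the other chromosomes (percentile 44.8 against 50.3, 42.9 against 49.3 and 43.4 against 51.1). The X chromosome had the lowest density in each list. Across the 20 chromosomes, which are not independent replicates, densities of 0.1 and 0.5 µM correlated with Pearson's r 0.985 (Spearman's rho 0.941), those of 0.1 and 1 µM with r 0.995 (rho 0.973), and those of 0.5 and 1 µM with r 0.992 (rho 0.974).

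**Figure D1:**
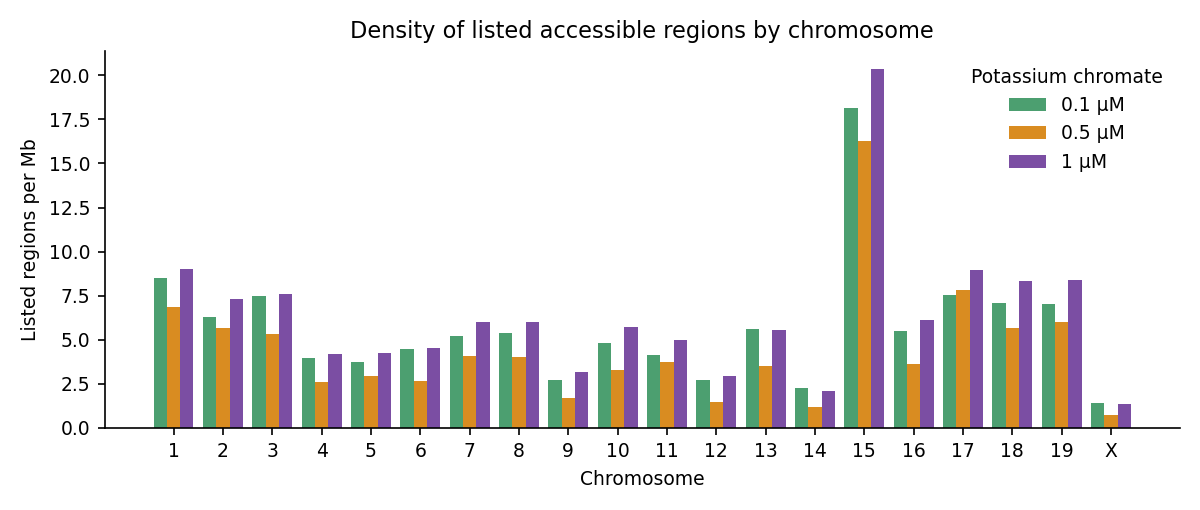
Bars give the number of listed regions per Mb (vertical axis) on each chromosome (horizontal axis) for the lists of 0.1, 0.5 and 1 µM potassium chromate. Chromosome 15 reaches 16.3 to 20.4 regions per Mb.

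Of the 10 regions with the best mean rank over all doses, 7 lay on chromosome 15, 6 at the end of a gene, and 4 met both conditions. The best of these ranks belonged to a region at 15:32920309-32921473, at an end of Sdc2, which encodes the cell surface heparan sulphate proteoglycan syndecan-2, with scores of 425, 240 and 427 in order of dose. The next lay between genes at 15:16403719-16405057, where Cdh9, a cadherin gene, is the nearest gene at 324 kb (scores 327, 233 and 485). Regions at an end of Emc2 (15:43476810-43478229), a subunit of the membrane protein insertase of the endoplasmic reticulum, and of Oxct1 (15:4025905-4028335), an enzyme of ketone body use, had scores of 335, 172 and 432 and of 267, 172 and 352. An end of Fbxo4 (15:3978894-3980228), a region inside Sybu (15:44698742-44699949) and one 105 kb from Zfat (15:68363037-68364060) completed those on chromosome 15. Outside it were Ppp2r1a (17:20944636-20945977), the scaffold subunit of protein phosphatase 2A, an end of Gm45871 (18:90579028-90580457) and a region inside Pigk (3:152813557-152814594).

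Other regions among the 10 highest scores of a list had very different scores elsewhere. The region at an end of Eny2 (15:44426883-44428731) scored 520 at 0.1 µM, where it was the highest, and 7 and 9 at 0.5 and 1 µM. Ebag9 scored 7, 201 and 12, Pja2 16, 181 and 15, Kyat3 8, 220 and 273, Med30 11, 167 and 311, Card6 7, 154 and 352, and Zfp622 253, 23 and 479. Zfp120 scored 153, 179 and 198. Such gaps are not read as differences between doses, because among matched regions of 1000 bp or more with scores over 4 times apart the lower score belonged to the narrower region in only 21.7% to 33.3% of pairs.

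The same regions were listed at several doses far more often than random placement gives. Of the 0.5 µM regions, 72.4% overlapped a 0.1 µM region (0.626% for random placements, a ratio of 116) and 79.4% a 1 µM region (0.716%, ratio 111). Of the 0.1 µM regions, 74.8% overlapped a 1 µM region (0.697%, ratio 107). Each comparison gave a permutation p of 0.001 (one-sided), the smallest that 1000 random placements allow. Merging all lists gave 21045 regions, of which 7263 (34.5%) were listed at all 3 doses. The 1 µM list alone gave 4057, the 0.1 µM list 3157 and the 0.5 µM list 1798, while 3142 were shared by 0.1 and 1 µM only, 1175 by 0.5 and 1 µM and 453 by 0.1 and 0.5 µM. All lists share the control libraries, so part of this excess may come from them. Sites open in this line without treatment would also give such an overlap, and no list of the untreated cells was used here. With random placement kept to the same gene end class the ratios fell to 32.9, 31.2 and 33.3 for 0.1 and 0.5, 0.5 and 1, and 0.1 and 1 µM, and with a reciprocal overlap of 50% they rose to 349, 338 and 358.

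**Figure D2:**
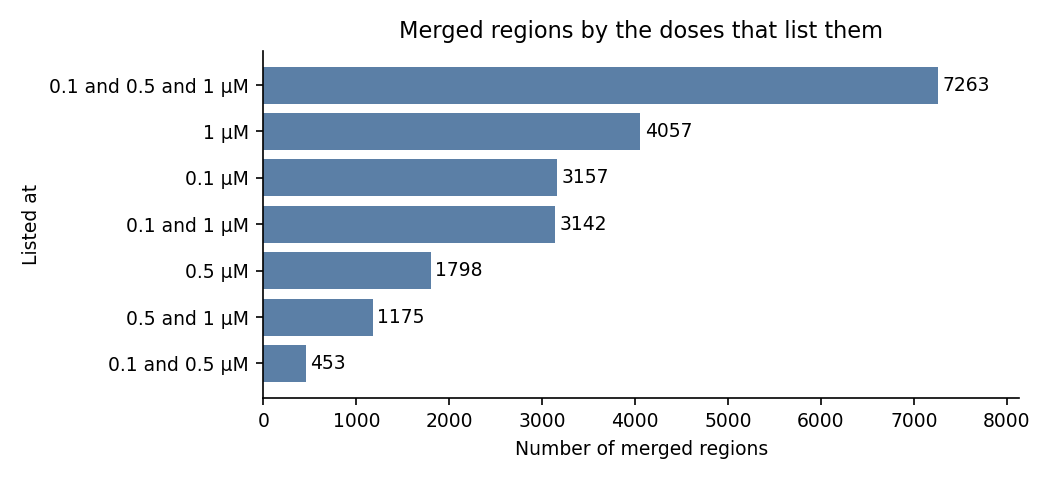
Bars give the number of merged regions (horizontal axis) for each combination of doses that lists them (vertical axis). The largest group, 7263 regions, is listed at every dose.

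Shared regions ranked higher than those listed at 1 dose. The median rank percentile of regions shared with at least 1 other list exceeded that of list-specific regions by 36.8 points at 0.1 µM, 29.9 at 0.5 µM and 36.5 at 1 µM (permutation test, p = 1e-05 each, the smallest possible). Ranked by width, the differences were 38.8, 33.9 and 38.3 points. Lists that end at a cut-off would give such a gap by themselves, since weak regions near it are easily missed in another list. Width is not a separate measure here, as wider regions had higher scores and more easily meet an overlap of 1 bp. Of the strongest 10% of regions by score, 98.8%, 99.6% and 99.2% were present in both other lists, and of the weakest 25%, 23.8%, 44.1% and 16.5%.

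Listed regions were concentrated at the ends of protein-coding genes. Gene ends held 28.3% of the 0.1 µM regions (95% interval 27.5 to 29.0), 34.0% of the 0.5 µM regions (33.2 to 34.9) and 29.5% of the 1 µM regions (28.7 to 30.2), against 2.99%, 3.04% and 3.01% for random placements, a ratio of 9.45, 11.2 and 9.78. Regions between genes made up 39.4%, 35.0% and 37.4%, and regions inside genes 32.3%, 31.0% and 33.2%, both below random placement (permutation p 0.002, two-sided, in each test of the 3 locations, the smallest possible). Regions present in both other lists lay at gene ends in 36.7%, 37.0% and 36.6% of cases, and regions in neither in 14.9%, 22.9% and 21.1% (Fisher's exact test, adjusted p 2.6e-120, 7.7e-31 and 1.9e-67). The former were also wider (median 457, 379 and 496 bp against 238, 238 and 253 bp). By score, gene ends held 40.9%, 46.0% and 44.0% of the strongest 10% and 24.1%, 28.7% and 25.2% of the weakest 25%. Sharing was therefore not separated from strength in this test. The share at gene ends was higher at 0.5 µM than at 0.1 µM by 5.76 percentage points (4.61 to 6.91, adjusted p 5.5e-22). At 1 µM it was higher than at 0.1 µM by 1.18 points (0.154 to 2.20, adjusted p 0.0317) and differed from 0.5 µM by -4.58 points (-5.71 to -3.45, adjusted p 7.2e-15). These tests and intervals between doses take the lists as independent. They are not, as 72.4% of the 0.5 µM regions overlapped a 0.1 µM region and 79.4% a 1 µM region. The difference between 0.1 and 1 µM no longer passed in the stronger 50% of the lists (1.13 points, adjusted p 0.158).

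At the level of genes, 4216 of 21631 protein-coding genes (19.5%) had a region within 1 kb of an end at 0.1 µM, 4055 (18.7%) at 0.5 µM and 4971 (23.0%) at 1 µM. All 3 doses shared 3069 genes, where independent lists would share 182. The pairs shared 3200 genes for 0.1 and 0.5 µM (790 if independent), 3752 for 0.1 and 1 µM (969) and 3559 for 0.5 and 1 µM (932). The shared controls, and sites open without treatment, may be part of the excess.

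Genes of the cell cycle held regions more often than other genes. Of 30 listed cell cycle genes, 18 had a region at 0.1 µM, 16 at 0.5 µM and 18 at 1 µM, or 60.0%, 53.3% and 60.0% against 19.4%, 18.7% and 22.9% of all other genes (adjusted p 5.84e-05, 0.000358 and 0.000349, Fisher's exact test as for all lists here). In 13 of them a region was listed at every dose. Examples were Mcm3, Mcm5 and Mcm6, subunits of the replicative helicase, with scores of 69, 57 and 75, of 72, 24 and 65 and of 10, 26 and 12 in order of dose, and Cdc20, an activator of the anaphase-promoting complex (26, 8 and 37). Scores of genes, here and below, are not read as differences between doses. At 0.5 µM the excess no longer passed in the wider 50% of the list (adjusted p 0.0714).

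AP-1 and immediate early genes, many of them coding for transcription factors induced by stress and growth signals, held regions in 12, 14 and 14 of 27 cases (44.4%, 51.9% and 51.9%, adjusted p 0.0132, 0.00131 and 0.00579). Atf3 (1:191183056-191183639 at 0.1 µM) scored 33, 42 and 46, Ier5 31, 18 and 61, Jun 31, 15 and 11, and Btg1 29, 20 and 34. The excess did not pass at 0.1 µM in the stronger 50% (adjusted p 0.248), or at 0.1 and 1 µM in the wider 50% (adjusted p 0.0672 and 0.311).

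Metal response genes, among them the metal-binding metallothioneins, metal transporters and heat shock chaperones, held regions in 9, 9 and 11 of 19 cases (47.4%, 47.4% and 57.9%, adjusted p 0.0190, 0.0166 and 0.00579). Mt1, a metallothionein, had a region at every dose (8:94178898-94179303 at 0.1 µM, scores 35, 15 and 26). Its neighbour Mt2 had none at a gene end, and the region of Mt1 lies within 10 kb of it. The copper transporter Atp7b scored 46, 24 and 43, the chaperone gene Dnajb1 26, 18 and 46. Hsph1, another, had a region at every dose, but not the same one throughout. Against random genes of the same chromosomes, the excess passed only at 1 µM (adjusted p 0.0314, with 0.0628 at 0.1 µM and 0.0610 at 0.5 µM), and with the gene body and 10 kb it did not pass at 0.1 µM (adjusted p 0.0655).

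CTCF, cohesin and chromosome structure genes held regions in 9, 9 and 13 of 24 cases, which passed at 1 µM (54.2%, adjusted p 0.00579) and not at 0.1 or 0.5 µM (both 37.5%, adjusted p 0.0700 and 0.0654). At 0.1 and 0.5 µM they passed with a window of 2.5 kb (adjusted p 0.0250 and 0.0231) and with the gene body and 10 kb (0.0124 and 0.00540), and at 0.1 µM in the stronger 50% (0.0253) and the wider 50% (0.0481). No test of a difference between doses passed, and few such tests could, as given below. Named members with a region at every dose were the condensin subunits Ncapg2 (scores 42, 35 and 38), Ncapd3 (21, 15 and 43) and Ncapg (24, 7 and 32) and the cohesin regulator Pds5b (43, 33 and 48). Of the 7 members with a region at every dose, only Pds5b and Yy1 were not condensin genes. The excess of this list therefore cannot be credited to CTCF or cohesin genes alone. Ctcf itself had no region within the gene or 10 kb of it in any list. Chromatin remodelling genes held regions in 15, 15 and 14 of 41 cases and passed at 0.1 and 0.5 µM (36.6% each, adjusted p 0.0284 and 0.0243), not at 1 µM (34.1%, adjusted p 0.154). In the stronger 50% of the lists neither passed (adjusted p 0.138 and 0.0733), nor did 0.1 µM with the gene body and 10 kb (0.167) or in the wider 50% (0.144). Smarca2, an ATPase of the SWI/SNF complex, scored 59, 53 and 77, the deacetylase gene Hdac2 48, 19 and 79, and Chd1 10, 21 and 41. The DNA demethylase gene Tet2 had a region at every dose, but not the same one throughout.

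Lists of oxidative stress, DNA damage and AHR genes did not pass, while single members had regions. NRF2 targets and oxidative stress genes held regions in 7, 10 and 10 of 30 cases (adjusted p 0.686, 0.101 and 0.249). With a window of 2.5 kb the 0.5 µM list passed (adjusted p 0.0186). Hmox1, heme oxygenase 1, had a region at every dose (8:75093329-75094006 at 0.1 µM, scores 52, 8 and 35). So did Nqo1, a quinone reductase (scores 7, 11 and 14), Sod1 (22, 26 and 40), Gclm, which takes part in glutathione synthesis (9, 13 and 12), and Nfe2l2, the gene of NRF2 (24, 7 and 28). Genes of p53 and the DNA damage response held regions in 12, 12 and 13 of 35 cases (adjusted p 0.0665, 0.0605 and 0.115) and passed at 0.1 and 0.5 µM in the stronger 50% (adjusted p 0.0277 and 0.0193). Ccng1 scored 95, 32 and 118, Gadd45a 45, 42 and 55 and Brca2 22, 34 and 9, while Cdkn1a, the p21 gene, had no region within the gene or 10 kb of it. AHR and xenobiotic metabolism genes held regions in 1, 5 and 5 of 22 cases (adjusted p 0.154, 0.672 and 1). Arnt (6 and 27), Cyp1b1 (12 and 26) and Ugt1a1 (9 and 11), whose end is shared with other Ugt1a genes, had regions at 0.5 and 1 µM, and Cyp1a1 had none within the gene or 10 kb of it in any list.

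Metabolic and liver genes did not pass within 1 kb. Oxidative phosphorylation genes held regions in 8, 7 and 7 of 26 cases (adjusted p 0.208, 0.393 and 0.686), with Uqcrc2, Atp5b, Atp5a1 and Ndufs1 at every dose. Glycolysis and gluconeogenesis genes had 6, 4 and 9 of 25 (adjusted p 0.683, 1 and 0.212) and passed at 1 µM with the gene body and 10 kb (16 of 25, adjusted p 0.0222), with Pgk1 at scores of 66, 47 and 90, Pfkm and Slc2a1 at every dose, and Hk2 at 0.1 and 1 µM. Cytosolic ribosomal protein genes had 8, 9 and 10 of 30 (adjusted p 0.435, 0.212 and 0.249), Rpl30, Rpl34, Rpl7 and Rps14 among them at every dose. Hepatocyte identity genes had 4, 4 and 7 of 34 (adjusted p 0.450, 0.450 and 0.877). Those at every dose were Apoa2, an apolipoprotein (scores 22, 24 and 80), the transcription factor genes Foxa2 (32, 24 and 23) and Cebpb, where the regions differ, and the bile acid receptor gene Nr1h4 (7, 8 and 15). Alb, the albumin gene, had none at a gene end.

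Genes of other lineages held few regions. Hox genes had regions in 0, 1 and 0 of 35 cases, against about 20% of other genes (adjusted p 0.00579, 0.0367 and 0.00158), Hoxa10 at 0.5 µM. Immune cell markers had 0 of 22 at every dose (adjusted p 0.0360, 0.0541 and 0.0166). Neuronal markers had 1, 0 and 0 of 22 (adjusted p 0.154, 0.0541 and 0.0166), with Snap25 at 0.1 µM. Markers of stellate cells, fibroblasts and endothelium had 0, 1 and 1 of 22 (adjusted p 0.0360, 0.154 and 0.0753), Dcn both times. In the stronger 50% of the lists, only Hox genes at 1 µM stayed below background, and with the gene body and 10 kb only Hox genes, at each dose. Hox genes lie side by side in clusters, so they are not independent, although the test treats them as if they were. With 10 kb either side, the region of Hoxa10 also counts for its neighbour Hoxa11. The p-values of the Hox list are therefore too small. With 2.5 kb, immune and neuronal markers passed at 0.5 µM (adjusted p 0.0211 each), while stellate cell, fibroblast and endothelial markers at 0.1 µM and neuronal markers at 1 µM no longer did (adjusted p 0.122 and 0.0517).

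**Figure D3:**
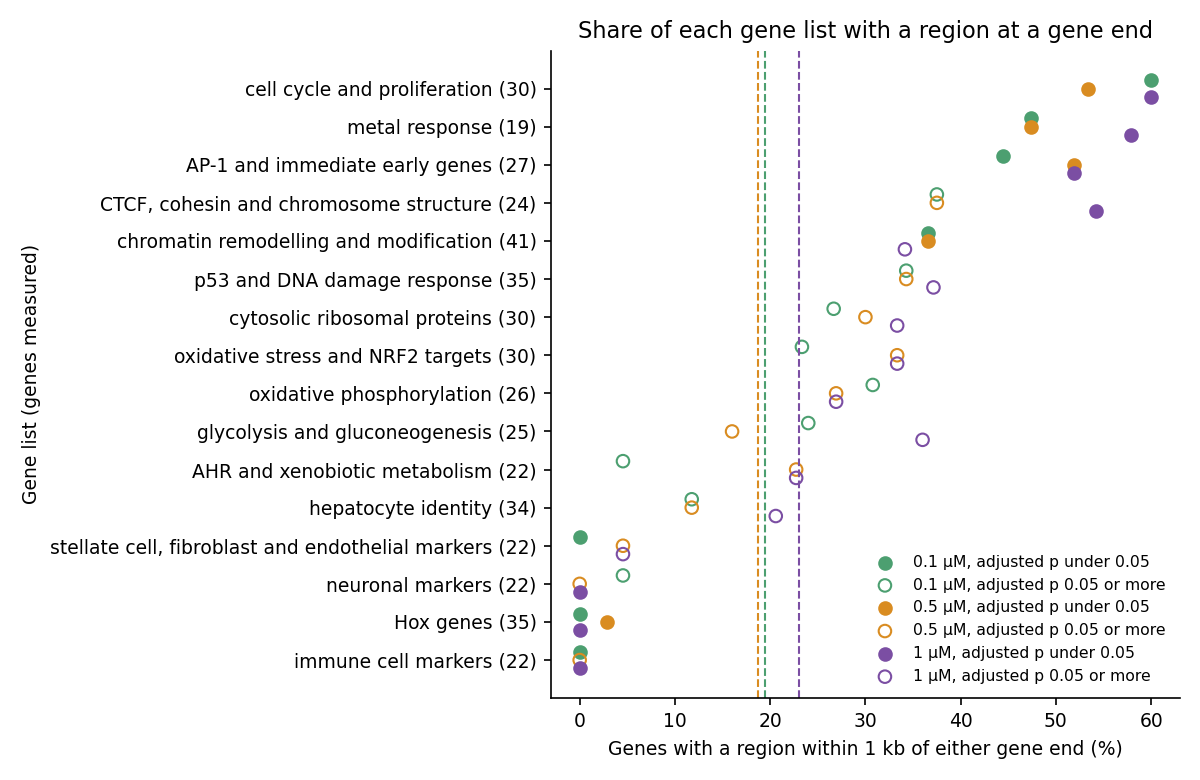
Points give the percentage of genes in each list (vertical axis, number of genes in brackets) with a region within 1 kb of either gene end (horizontal axis), coloured by dose. Filled points have an adjusted p under 0.05 against all other genes, and dashed lines mark all protein-coding genes (19.5%, 18.7% and 23.0%).

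In all, 4 of 16 lists lay above background at each dose, and 3, 1 and 3 below it. Between doses, among genes with a region at 1 dose of a pair, 0 of 48 Fisher's exact tests of a list against all other genes passed after adjustment. A list had at most 8 such genes in a test, and only 4 tests could have passed as the single difference even with all of them at 1 dose, so this does not show that the lists were alike. At an unadjusted p under 0.05 there was 1, the AHR list between 0.1 and 0.5 µM (Fisher's exact test, p = 0.0434). Its genes include Ugt1a1 and Ugt1a6a, which share an end and the same region at 0.5 µM. That region was counted for both, so this p is too small.

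Along the genome, 3 windows of 1 Mb out of 1307 held more regions at 0.5 µM than the other lists would give. The window at 132 to 133 Mb of chromosome 1 held 26, 70 and 37 regions in order of dose, a share 3.02 times that of the other lists (Fisher's exact test, adjusted p 7.2e-07). It includes Nfasc, a neural cell adhesion gene, with 7, 19 and 7 regions inside it. The window at 5 to 6 Mb of chromosome 17 held 21, 79 and 43 (3.36 times, adjusted p 3.2e-09), with 5, 22 and 10 inside Zdhhc14, a palmitoyltransferase gene. Arid1b, a SWI/SNF subunit gene that extends past the window, held 9, 24 and 19 over its whole length. At 167 to 168 Mb of chromosome 2, around Cebpb and the phosphatase gene Ptpn1, 38, 87 and 72 regions were listed (2.15 times, adjusted p 0.000174). The windows on chromosomes 17 and 2 held fewer regions at 0.1 µM than the other lists give (0.323 and 0.448 times, adjusted p 0.000111 and 0.00209). Those other lists include the 0.5 µM list, so these ratios are not separate from its excess. No window passed at 1 µM, where 6 had an unadjusted p under 0.05. These windows were picked from the same lists that give the ratios, and this selection inflates them. The tests also take the lists as independent, although many regions are listed at several doses.

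**Figure D4:**
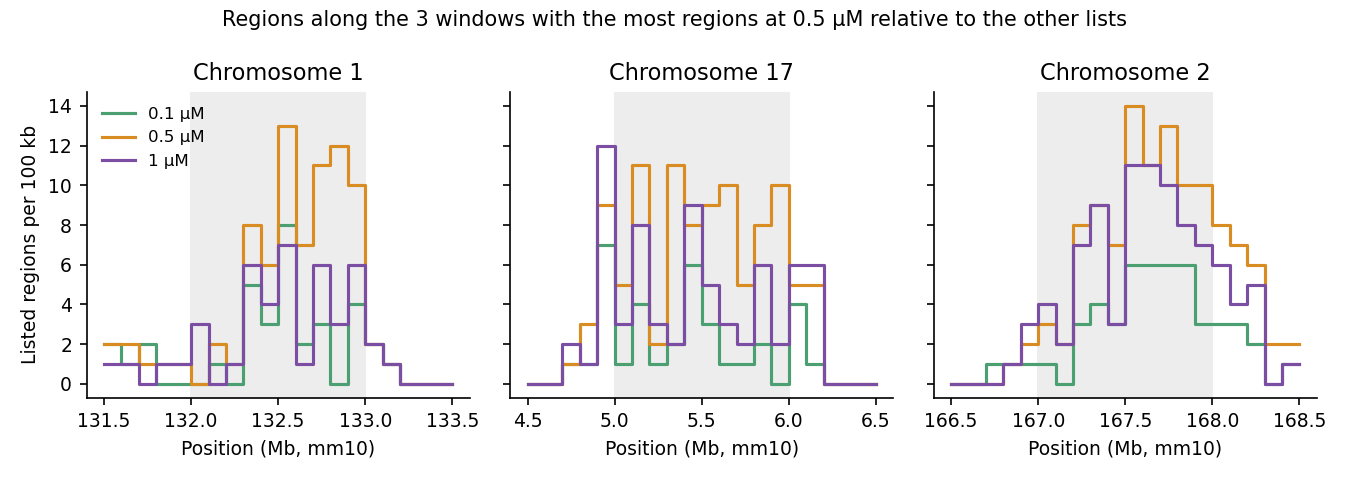
Steps give the number of listed regions per 100 kb (vertical axis) along the mm10 position in Mb (horizontal axis) for each dose, around the 3 windows of 1 Mb (grey) with more regions at 0.5 µM. Inside them the 0.5 µM list holds 70, 79 and 87 regions on chromosomes 1, 17 and 2.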

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

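All tests of this part were chosen after the lists had been seen. The values decided by the spread of chromosome 15 over 5 Mb windows, its split by location and the covered length of the 3 windows had not been seen when those tests were set. The tests on regions per gene, on the shared control and on ranks within each window, the comparison of both directions for missing regions, and all rankings by width in this section, were set after the values they use, or related ones, were known.

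The share of regions at gene ends differed between each pair of lists, by 5.76 percentage points (0.5 minus 0.1 µM), 1.18 (1 minus 0.1 µM) and -4.58 (1 minus 0.5 µM). Regions present in both other lists are the same places and lay at gene ends about equally often at each dose (36.7%, 37.0% and 36.6%). They made up 51.6%, 68.0% and 46.3% of the lists in order of dose. The difference thus lies in the remaining regions and in how many of them each list holds. The 0.5 µM list is also the shortest. Regions of the 1 µM list that were missing at 0.5 µM ranked 38.4 percentile points lower within the 1 µM list than those found in both (39.7 by width). Lower power at 0.5 µM stays open, since the gap stood in the other direction too: regions of the 0.5 µM list missing at 1 µM ranked 34.5 points lower (34.8 by width). A shorter list of stronger regions could raise the share at gene ends, and this also stayed open. As many of the strongest 1 µM regions as the 0.5 µM list holds, 11130, lay at gene ends in 31.5% of cases by score, 1.33 to 3.79 points below the 34.0% at 0.5 µM, and in 33.0% by width, where the interval of the difference (-0.243 to 2.24) includes 0. Among the 5565 regions of each list with the highest score, the share was 38.9% at 0.5 µM. It was 35.6% at 1 µM and 33.5% at 0.1 µM (Fisher's exact test against 0.5 µM, adjusted p 0.00086 and 2.9e-08). By score, an equal number of regions thus did not remove the difference, while the comparison by width leaves the question open. These tests and intervals take the lists as independent, although many of their regions overlap. Dose itself remains an untested explanation, and with 1 list per dose it cannot be separated from library quality.

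In 3 windows of 1 Mb the 0.5 µM list held a larger share of its regions than the other lists did, by 3.02 times on chromosome 1, 3.36 on chromosome 17 and 2.15 on chromosome 2. The 0.1 µM list held 0.323 times the share of the others, the 0.5 µM list among them, on chromosome 17 and 0.448 times on chromosome 2. Control coverage that acts alike on all lists would give each list the same share in these windows. The largest p of the 3 windows at 0.5 µM, adjusted over all windows and lists, was 0.000174 (Fisher's exact test). The windows were picked by this p, so it restates the pattern and is not a separate test of this explanation. An unequal action of the control was not tested. Regions split into more pieces would leave the covered length alike, and relative to the whole lists it was 2.60 times that of the other lists. A rise in signal along the segment, as a hypothesis, would lift the ranks of regions shared by 0.5 and 1 µM: relative to 8742 such regions elsewhere, this gain was 9.75 points on chromosome 2 (53 regions, permutation p adjusted over the windows 0.0282, by width 6.83, p 0.0713), 7.23 on chromosome 17 (27 regions, p 0.195, by width 13.5, p 0.0399) and -1.38 on chromosome 1 (15 regions, p 0.816, by width 7.35, p 0.234), so it stays open on all 3, as none passed by both score and width and the windows were picked from the same lists. An effect of the dose and a change in DNA copies in the treated cultures were not tested.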

How the results depend on the processing

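Of the alternatives, rankings by width (except for the ranks of shared regions), random shifts, gene draws from the same chromosomes, and runs without chromosome 15 or receptor genes were chosen after seeing the data. Among the main results, 122 values under an alternative kept their direction and side of the threshold or stayed within 1.5 times, 14 counts moved further and 2 tests no longer passed; no result reversed. The overlap ratios ranged from 31.2 to 358 and all passed. The stronger 50% of each list holds 7201, 5565 and 7947 regions by construction. The 1.18 point difference in gene end share between 0.1 and 1 µM became 1.13 in the stronger 50% (adjusted p 0.158) and 1.14 in the wider 50% (adjusted p 0.189). In these 2 settings the difference itself hardly moved, and fewer regions were tested. With equal numbers of strongest regions, a setting outside the count of 2 tests above, it grew to 2.07 points and did not pass either (adjusted p 0.0519). The number of gene lists above background stayed within 1.5 times of 4 throughout. The number below background, 3, 1 and 3 in order of dose, was less stable. At 0.5 µM it became 3 with a 2.5 kb window, 3 against genes of the same chromosomes and 3 without receptor genes. With the gene body and 10 kb it became 1 at 0.1 µM and 1 at 1 µM. In the stronger 50% it became 0, 0 and 1, and in the wider 50% 1, 0 and 1, where a lower background leaves less room for a deficit. Otherwise the cause was not tested. Over single lists and doses, 28 tests lost and 16 gained a call, and 26 of the counts of doses for named genes changed. No paired analysis was possible because each dose has 1 list with no replicate numbers. For the same reason no library could be left out. The motif alternatives were not run, as no sequence was used here. Read depth is unknown, so how far it sets the lengths of the lists cannot be given.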

Other observations

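The gene families in this paragraph were chosen by their symbols after seeing the data, and tested by Fisher's exact test with adjustment over 16 families and 3 doses. Zinc finger protein genes with a Zfp symbol had a region at a gene end in 144, 132 and 160 of 397 cases in order of dose (36.3%, 33.2% and 40.3%, against 19.2%, 18.5% and 22.7% of other genes, adjusted p 2.2e-14, 2.4e-11 and 4.8e-14). Genes of mitochondrial ribosomal proteins had one in 34, 31 and 36 of 78 (43.6%, 39.7% and 46.2%, adjusted p 3.9e-06, 4.6e-05 and 3.0e-05). Regions were rare at olfactory receptor genes, with 4, 3 and 4 of 1110, at vomeronasal receptor genes, with 1 of 355 at each dose, and at protocadherin genes, with 4, 2 and 3 of 69. Cytochrome P450 genes, many of them liver enzymes of drug and steroid metabolism, also lay below background with 8, 6 and 8 of 99 (adjusted p 0.00646, 0.00103 and 0.000440), as did keratins with 1, 3 and 5 of 109 and serpins with 2, 2 and 7 of 63. UDP glucuronosyltransferase genes, some of which share an end, had 3, 9 and 10 of 22, above background at 0.5 and 1 µM (adjusted p 0.0246 and 0.0352) and not past the threshold at 0.1 µM (adjusted p 0.686). Where genes share an end, as Ugt1a1 and Ugt1a6a do, 1 region counts for each of them. The test treats such repeated hits as independent, so its p-values for this family are too small. Kruppel-like factors had 8, 7 and 8 of 17 (adjusted p 0.0186, 0.0420 and 0.0551) and tripartite motif genes 22, 13 and 22 of 68 (adjusted p 0.0246, 0.896 and 0.112). Solute carriers, proteasome subunits, forkhead factors and kinesins passed at no dose. Histone genes, which are near-identical copies and thus uncertain, had 17, 10 and 33 of 101: not past the threshold at 0.1 µM (adjusted p 0.686), below background at 0.5 µM (adjusted p 0.0358) and above it at 1 µM (adjusted p 0.0386), and no difference between doses was tested for any family.

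The genes with the most regions within the gene and 10 kb either side in every list were mainly long genes of chromosome 15. Csmd3 held 41, 20 and 31 regions over 1212 kb, Trio 18, 21 and 22, and Ctnnd2 22, 18 and 29. Off chromosome 15, Stard13 on chromosome 5 held 26, 19 and 24, and Alad on chromosome 4, an enzyme of heme synthesis spanning only 14.1 kb, held 12, 14 and 15.

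The excess on chromosome 15 was weighed against technical explanations. More genes do not account for it, since regions per protein-coding gene were at least 4.04 times those of other chromosomes. Nor do a few clusters, since at least 89.5% of its 5 Mb windows lay above the genome's median window. Extra copies of the chromosome in this line, or another chromosome-wide rise in read depth, may be the cause, but the excess was uneven: 1.64, 1.95 and 1.62 times at gene ends against 4.95, 6.40 and 5.08 times between genes, up to 3.28 times apart, and no read depth was at hand to decide. The excess stood in every treated list, so no comparison of doses bears on it, and no biological explanation was tested.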
